A study of Mus musculus with 16 samples.

How the data were processed

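Quadriceps RNA of 16 mice in 4 groups (WT or KO for Klf15, vehicle or 2 mg/kg dexamethasone, sampled at 8 h) was measured with Agilent 4x44K mouse arrays, 4 animals per group and 1 array per animal. Per the labels' protocols, amplified cDNA was made with a whole-transcript amplification kit and labelled with Cy3 by a 1-colour kit, and tissue was assessed at 0 and 8 h; each sample analysed here has a time of 8 h in its treatment label. Groups and replicate numbers were taken from the sample titles.

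The deposited scanner files hold spot intensity on a linear scale, 1 file per array. Per the file headers they were made with Feature Extraction 10.7.3.1 and a grid of build mm9; the processed signal is background-subtracted and spatially detrended, and is not normalized between arrays. A deposited table of the whole series holds log2 values of the same arrays. Its columns had medians from 6.85 to 6.87 and ranked probes as the scanner's median signal did (Spearman correlation of 1 on every array), and sorted values differed by at most 0.0731 between an array and the mean of all arrays, so the scale was taken as log2 with near-equal distributions. Its base, centring and steps are not given in the sources used here, and with 1 dye it has no direction of ratio. No column of per-sample values was left unused for want of a sample.

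The main values were log2 of the processed signal minus each array's 75th percentile over non-control probes. Control spots and spots marked as outliers were left out, spots of 1 probe were averaged, and probes well above background on at least 4 of 16 arrays were kept. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6. Of 41174 probes 24844 were given a symbol, out of 26382 with a RefSeq accession, and the others kept the accession in the files. Because the table's build differs from that of the files, it served for names and for which genes neighbour each other, and no coordinates are given. For several probes of 1 gene the brightest was used; over the named genes that passed, the other probes had the same sign in 28 of 29 cases under dexamethasone in KO, 30 of 32 in WT, 9 of 9 for KO against WT under vehicle, 6 of 6 under dexamethasone and 8 of 8 for the average, and none passed in the opposite direction. Their change was less than 0.5 times that of the probe used in 8 of 29, 9 of 32, 4 of 9, 3 of 6 and 5 of 8 cases, in the same order. A group whose arrays were all below background gives only a bound, written as at least N-fold. It compares the mean of the bright group with the mean, per array, of the higher of the dim probe's signal and the lowest signal of any probe well above background.

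Tests were made in R 4.3.3 with limma 3.58.1: 4 group means were fitted to all 16 arrays, contrasts were moderated with eBayes, and p-values were adjusted by the Benjamini-Hochberg method over 25196 features with a threshold of 0.05, two-sided. The contrasts were dexamethasone against vehicle in each genotype, KO against WT under each treatment and averaged over treatments, and their interaction. A total of 28 gene lists were fixed from textbook knowledge before the data were examined, and were tested with camera (preset correlation 0.01) in 6 comparisons, adjusted over all 168 tests; camera with an estimated correlation and fry were run beside it. Of 46 called tests, 4 held with an estimated correlation: interferon response with dexamethasone in KO, and amino acid catabolism for KO against WT under each treatment and averaged. Genes named are, per comparison, the 10 largest rises and 10 largest falls among features with a gene symbol that passed and whose groups did not overlap, up to 4 members past the threshold of each list, and Klf15, Fkbp5, Per1, Tsc22d3, Zbtb16, Pdk4, Fbxo32, Trim63, Bcat2, Slc25a20 and Prodh; where nothing passed, the 10 features with the smallest p were eligible. Under dexamethasone in WT, Cth, Spop, Slx4ip and Itih5 values are given with the interaction they belong to. Named members of families with near-identical copies are uncertain.

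The arrays lay on 8 slides that each held 1 to 3 arrays and, except for slides with 1 array, more than 1 group. Slide was fitted as a fixed block and as a random block (consensus correlation 0.575), and values within slides are given. In the fixed-block fit an array alone on its slide adds nothing to a contrast. These were WT dexamethasone replicates 1 and 3 and KO vehicle replicate 2. The WT dexamethasone group then rests on replicates 2 and 4, of which only replicate 2 shared a slide with WT vehicle. Signs on a slide were also tested for features called without its arrays, a test added after the data were seen. The scans fell on 2 dates, with 1 array on the second. Feature Extraction marked 3 arrays for evaluation, and they were kept. The other alternatives were other scalings (median, quantile), normexp background correction, the deposited log2 values, other filters on dim probes, the mean of all probes of a gene, fits of only the groups compared, array weights, eBayes with trend, the replicate number as a block and leaving out each array. Those added after the data were seen were leaving out the 3 marked arrays, slide 7 or the 2 arrays with the highest neutrophil markers, and the median signal with local background subtracted or uncorrected. The planned normexp step used the median signal, since the scanner files give no mean signal, and gene names came from accessions, since they have no gene name column. The code was tested on simulated data of 25115 features with 200 changed, where 53.7% of features changed by 1 log2 unit were recovered for dexamethasone in WT, 52.2% in KO, 53.7% for KO against WT under vehicle and 52.2% under dexamethasone, with independent arrays. Slide as a fixed block recovered 2.99%, 11.9%, 11.9% and 0% of them, and 32.8%, 47.8%, 47.8% and 32.8% where arrays of a slide were correlated. With 200 changed features, fewer than passed in some comparisons here, these shares compare the fits and do not give the recovery in these data.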

Results

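Quadriceps muscle was examined in wild-type (WT) mice and in mice with a targeted Klf15 gene (KO), 8 h after a single intraperitoneal dose of vehicle or of 2 mg/kg dexamethasone, a synthetic glucocorticoid. Klf15 encodes a zinc-finger transcription factor. RNA of 16 animals, 4 in each of 4 groups, was amplified, labelled with 1 dye and hybridised to 16 arrays on 8 slides. The comparisons address how muscle transcripts responded to the glucocorticoid and whether the response depended on Klf15. On each array 66.3% to 80.6% of spots were well above background, and the 75th percentile of intensity ranged from 554 to 1169. The correlation between arrays of a group ranged from 0.933 to 0.990 across features. A total of 25196 features were tested, of which 15177 had a gene symbol. The number of arrays, 4 per group, limits the precision of each value. Log2 changes are given with their standard error (SE), and each comparison of groups rests on n = 4 arrays per group unless stated. With slide as a fixed block, arrays alone on a slide drop out, so n is smaller for WT dexamethasone and KO vehicle.

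Some arrays stood apart from others of their group. Markers of neutrophils were raised on WT dexamethasone replicate 3 and KO dexamethasone replicate 1, with list medians 7.11 and 5.72 log2 units above the mean of all 16 arrays. The next highest array, WT dexamethasone replicate 1, lay at 0.68. The erythroid marker median was 1.84 and 1.43 on the same arrays. The slow-fibre contractile genes varied within every group, with array medians from -1.48 to 1.20. The first principal component, 34.3% of the variance, set the 3 arrays of slide 7 and WT dexamethasone replicate 1 apart from the other 12.

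**Figure D1:**
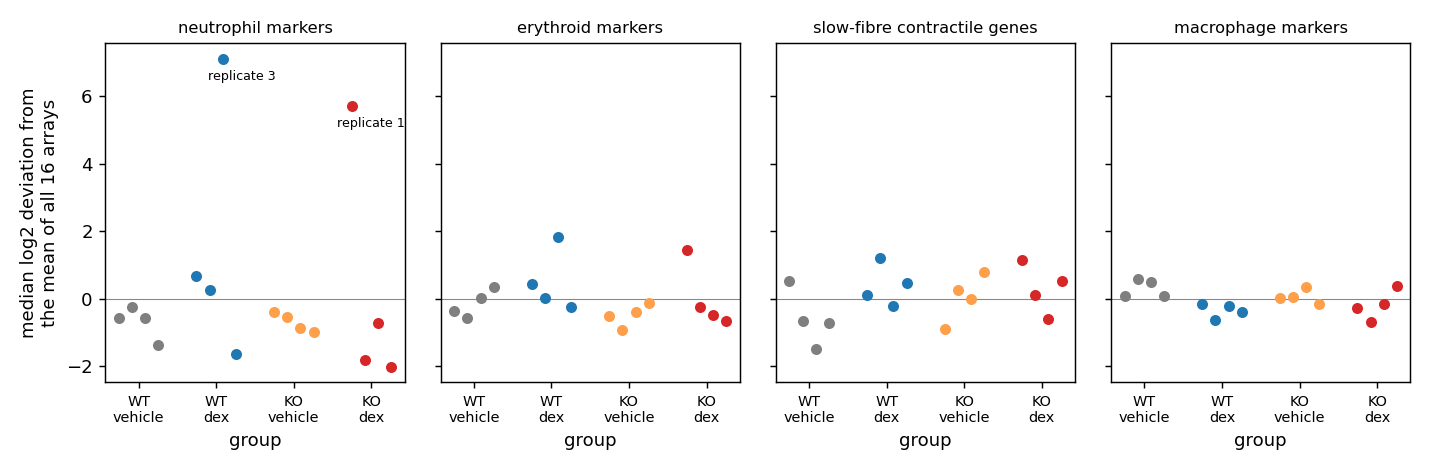
Median log2 deviation of neutrophil, erythroid, slow-fibre and macrophage genes from the mean of all 16 arrays (vertical axis) in the 4 groups (horizontal axis); each point is 1 array. Neutrophil markers reached 7.11 on WT dexamethasone replicate 3 and 5.72 on KO dexamethasone replicate 1.

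Klf15 signal was lower on all 8 KO arrays than on any of the 8 WT arrays, for both of its probes. With probe A_52_P64383, used for the gene, the level relative to the array's 75th percentile was 3.34 ± 0.40 (log2, SD, n = 4) in vehicle-treated WT muscle and -0.63 ± 0.50 (SD, n = 4) in vehicle-treated KO muscle. After dexamethasone the levels were 4.35 ± 0.36 and 0.55 ± 0.19 (SD, n = 4 each). KO levels were thus 15.6-fold lower under vehicle and 13.9-fold lower under dexamethasone. Probe A_51_P299339 was 8.67-fold and 14.3-fold lower. Over all 16 arrays the exact permutation test of KO against WT gave p = 0.0001554 for each probe (two-sided), the smallest that 12870 permutations can give. The targeted allele's position relative to the probes is not given in the sources used here. Within slides, the KO difference of the gene's probe was -3.36, -4.25 and -4.08 under vehicle (slides 4, 6 and 7) and -3.77 under dexamethasone (slide 8).

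Dexamethasone raised Klf15 2.02-fold in WT muscle (log2 change 1.01, SE 0.26, adjusted p 0.023, and up to 0.066 with 1 array left out) and 2.26-fold in KO muscle (1.18, SE 0.26, adjusted p 0.010). The second probe changed 2.19-fold in WT (adjusted p 0.017) and 1.33-fold in KO (adjusted p 0.465), so the rise in KO passed the threshold with 1 of 2 probes.

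**Figure D2:**
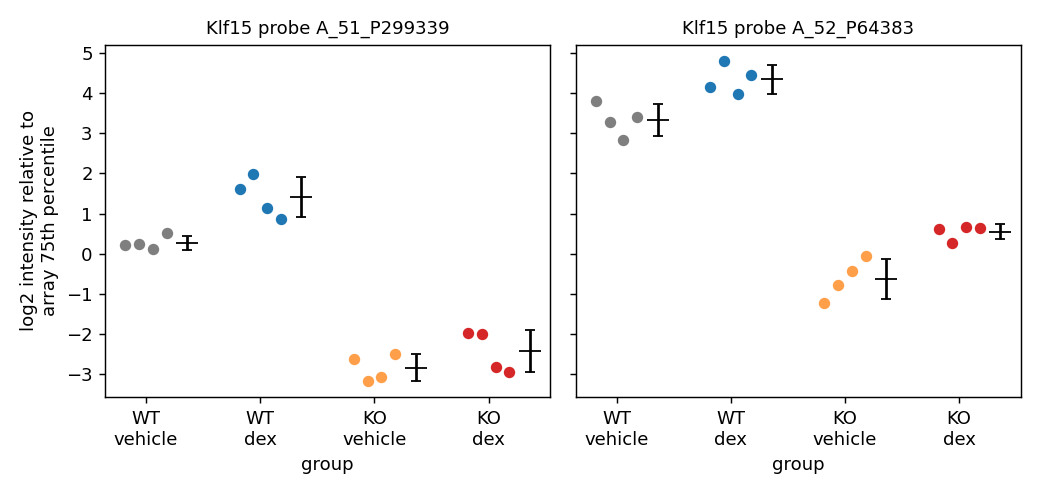
Klf15 signal (vertical axis: log2 intensity relative to the 75th percentile of the array) in the 4 groups (horizontal axis) for its 2 probes. Points are arrays and the black marks are group means with SD (n = 4). All KO arrays lay below all WT arrays.

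In WT muscle Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose 81.9-fold with dexamethasone (log2 change 6.36, SE 0.37) and the orosomucoid gene Orm3 rose 54.5-fold (5.77, SE 0.53). The metallothionein gene Mt2 rose 10.8-fold (3.43, SE 0.31) and the zinc transporter gene Slc39a14 rose 9.40-fold (3.23, SE 0.17). Ptprf (11.3-fold), Ptgds (9.82-fold) and Kcnk1 (9.36-fold) were also among the 10 largest rises, as were Slc4a7 (26.1-fold), whose SE of 1.14 was the widest of them and whose other 2 probes gave log2 changes of -0.22 and 0.35 (adjusted p 0.323 and 0.136), and Greb1 (10.4-fold) and Dgki (9.36-fold), which were well above background on 2 and 1 of the 4 vehicle arrays. Without WT vehicle replicate 2 the rise of Greb1 was 5.99-fold, and within slide 5 its log2 change was 1.62. The prion-like gene Prnd was not well above background on any dexamethasone-treated WT array and was at least 12.2-fold lower. The macrophage gene Aif1 fell 8.26-fold (-3.05, SE 0.40), and the chemokine genes Ccl7 and Ccl2 fell 7.73-fold and 6.05-fold. Gbp4, an interferon-induced GTPase gene, fell 7.69-fold. Ccl7 and Gbp4 were well above background on 2 and 3 of the 4 dexamethasone arrays. Lalba (9.59-fold), Prss42 (6.96-fold), Camkv (5.89-fold), Fam167a (at least 2.32-fold) and Ugt2a1 completed the 10 largest falls. The fall of Camkv was 3.15-fold without WT vehicle replicate 1. Prss42 changed by -0.44 within slide 5 and by -3.58 without WT dexamethasone replicate 2, and no longer passed when any 1 of 13 arrays was left out (adjusted p up to 0.123). Prss42 and Camkv were well above background on 1 of the 4 dexamethasone arrays each, and Ugt2a1 on none of them, with no fold given. Orm3, Gbp4 and Ugt2a1 belong to families with closely similar copies and are uncertain. Of 24 named genes with other probes, 11 passed with the probe used alone, among them Slc4a7, Ugt2a1, Bcat2, Hspb7, Slc38a2, Btg2, Col4a1 and Eif4ebp1.

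Of 24 measured glucocorticoid receptor targets, 15 rose in WT muscle and none fell (18 and 0 adjusted over the list alone). Fkbp5, a co-chaperone of the receptor, rose 7.91-fold (2.98, SE 0.16), the cell-cycle inhibitor Cdkn1a 7.86-fold, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, 3.08-fold. Per1 (log2 change 0.29, SE 0.14, adjusted p 0.23) and Tsc22d3 (0.29, SE 0.13, adjusted p 0.19) did not pass, and Zbtb16 was not analysed here. The list median was 0.90 (camera adjusted p 2.5e-17; adjusted p = 0.066 with an estimated correlation), 0.91 with slide as a block and 0.95 within slide 5, the only slide with both WT groups. Of 23 atrophy, ubiquitin ligase and autophagy genes 6 rose (11 adjusted over the list alone). They included the transcription factor Foxo1 (5.03-fold), the muscle ubiquitin ligase Trim63 (3.06-fold) and the growth inhibitor Mstn (1.90-fold), whereas Fbxo32 gave 1.09 (SE 0.36, adjusted p 0.071). The median was 0.26 (camera adjusted p 2.3e-08; adjusted p = 0.19 with an estimated correlation), 0.31 with the block and 0.41 within the slide.

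Of 29 genes of branched-chain and other amino acid catabolism 9 rose in WT muscle and none fell (11 and 0 adjusted over the list alone). Bcat2, the mitochondrial branched-chain aminotransferase, rose 1.74-fold (0.80, SE 0.19), Prodh, proline dehydrogenase, 1.60-fold, and Oat, ornithine aminotransferase, 1.52-fold. The median was 0.28 (camera adjusted p 1.3e-09; adjusted p = 0.050 with an estimated correlation), 0.22 with slide as a block and 0.26 within slide 5. Of 34 fatty acid genes 7 rose and 1 fell (12 and 1 adjusted over the list alone). The lipid droplet gene Plin5 rose 4.02-fold, the mitochondrial carrier Ucp3 3.46-fold, the nuclear receptor Ppara 2.89-fold and the carnitine carrier Slc25a20 1.54-fold. The median was 0.26 (camera adjusted p 1.8e-06; adjusted p = 0.56 with an estimated correlation), 0.26 with the block and 0.25 within the slide. Of 23 glucose and glycogen genes 2 rose, Ppp1r3c (4.28-fold), a glycogen-targeting subunit of protein phosphatase 1, and Pfkfb1 (1.61-fold; 3 adjusted over the list alone). Of 30 citric acid cycle and respiratory chain genes 2 rose, Sdha (1.33-fold) and Ndufa9 (1.28-fold), and 0 passed adjusted over the list alone. The medians of these 2 lists were 0.09 and 0.07 (camera adjusted p 0.042 and 0.033; adjusted p = 0.80 and 0.82 with an estimated correlation), -0.01 and -0.04 with the block, which ended both calls, and 0.09 and -0.03 within the slide.

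Of 22 interferon-response genes 19 fell in WT muscle and none rose (20 and 1 adjusted over the list alone), among them Iigp1 (4.69-fold, uncertain because of similar copies), Oasl2 (3.33-fold) and the immunoproteasome subunit Psmb9 (3.08-fold). The median was -1.16 (camera adjusted p 4.0e-13; adjusted p = 0.096 with an estimated correlation), -1.24 with slide as a block and -1.25 within slide 5. Of 19 inflammatory cytokine and NF-kB genes 6 fell (8 adjusted over the list alone), with the chemokine gene Cxcl9 3.64-fold lower and Cxcl10, not well above background after dexamethasone, at least 5.31-fold lower. The median was -0.60 (camera adjusted p 0.0031; adjusted p = 0.19 with an estimated correlation), -0.57 with the block and -0.80 within the slide. Of 15 macrophage markers 6 fell (8 adjusted over the list alone), including Folr2 (2.26-fold), Adgre1 (2.18-fold) and the complement gene C1qc (1.98-fold). The median was -0.61 (camera adjusted p 0.00017; adjusted p = 0.56 with an estimated correlation), -0.74 with the block and -0.72 within the slide.

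Among heat shock and unfolded protein response genes 4 of 18 rose and 1 fell (4 and 3 adjusted over the list alone), with Hspb7 2.66-fold and Hspb1 1.76-fold higher. The median was 0.23 (camera adjusted p 0.023; adjusted p = 0.48 with an estimated correlation), 0.09 with slide as a block, which ended the call, and -0.07 within slide 5. No slow-fibre contractile gene of 12 passed, although the list was shifted by a median of 1.02 (camera adjusted p 0.010; adjusted p = 0.74 with an estimated correlation), 1.97 with the block and 1.92 within the slide. Of 16 clock genes 4 fell, including the output factor Dbp (2.36-fold) and Per3 (2.15-fold), and Arntl, which encodes the core factor BMAL1, rose 2.12-fold (2 higher and 5 lower adjusted over the list alone); the list was not called (camera adjusted p 0.50). Of 15 immediate-early genes 4 rose, including Maff (3.33-fold) and Btg2 (2.36-fold), with no call (5 adjusted over the list alone, camera adjusted p 0.074). The other lists were not called in WT muscle. Their members rose and fell as follows: 3 and 1 of 16 dystrophin-associated genes (Dtna 1.64-fold higher), 3 and 1 of 19 IGF1, insulin and mTOR genes (Irs1 2.64-fold lower, Eif4ebp1 1.86-fold higher), 4 and 1 of 19 amino acid stress genes (Slc38a2 1.80-fold higher), 2 and 3 of 20 extracellular matrix genes (Lum 2.24-fold lower, Col4a1 1.58-fold higher), 2 and 1 of 15 myogenesis genes (Myf6 1.71-fold higher), 1 and 1 of 10 smooth muscle and pericyte markers (Myh11 1.67-fold higher, Notch3 1.73-fold lower), 0 and 1 of 13 endothelial markers (Ptprb 1.61-fold lower) and 1 and 0 of 11 adipocyte markers (Lep 2.33-fold higher). Adjusted over the list alone, these counts were 4 and 2, 3 and 2, 4 and 1, 2 and 5, 2 and 2, 1 and 1, 0 and 1, and 1 and 0, in the same order. No member passed among 12 fast-fibre, 14 lymphocyte, 9 neutrophil, 4 erythroid, 9 nerve, 8 tendon and 4 sex-linked genes. The neutrophil median was 1.53 (camera adjusted p 0.080), with WT dexamethasone replicate 3 far above the other arrays.

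In all, 2709 features passed in WT muscle (limma, adjusted p < 0.05), 1283 higher and 1426 lower. With slide as a block, where WT dexamethasone replicates 1 and 3 carry no weight, 766 passed, 656 of them among the 2709. All 84 named results kept their sign with the block, 33 of them past the threshold. They were chosen for passing on these same arrays, so the kept signs are partly built in. Of 1871 features called without the arrays of slide 5, 96.5% of the higher and 91.9% of the lower had the same sign on that slide. In simulated data with 200 features changed, the fit with slide as a block recovered 2.99% to 32.8% of changes of 1 log2 unit. The lower value was for independent arrays and the higher for arrays correlated within slides. Far more features passed here, so these shares do not tell how many calls the block lost for want of power. Leaving out a single array ended the call of 31 of the 84 named results for at least 1 array, and without WT vehicle replicate 2 the count was 1627. The share of higher features was 47.4% but 82.8% when arrays were scaled to their median, under which the median of all features moved from -0.07 to 0.17.

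In KO muscle the largest responses again included Lcn2, which rose 84.6-fold (SE 0.37 on the log2 scale), and Orm3, which rose 48.0-fold (5.59, SE 0.53). Greb1, not well above background on any vehicle-treated KO array, was at least 15.3-fold higher. The transcription factor Sox4 rose 15.7-fold, Ptgds 15.7-fold, Mt2 13.7-fold, Slc39a14 11.9-fold, Dgki 11.7-fold (2 of 4 vehicle arrays well above background; 7.28-fold without KO vehicle replicate 2), Cmtm2a 11.6-fold and Ptprf 11.2-fold. Prnd was at least 13.4-fold lower, the hyaluronan synthase gene Has3 at least 5.59-fold, Lrrc55 at least 3.29-fold, the oestrogen receptor gene Esr2 at least 3.22-fold and Dhrs2 at least 2.27-fold, none of them well above background after dexamethasone. Gbp4 fell 11.5-fold (2 of 4 dexamethasone arrays well above background), Fam83d 7.70-fold, Aif1 7.32-fold, Pcdh12 6.68-fold and the T-cell receptor chain gene Cd247 6.18-fold. Of 23 named genes with other probes, 11 passed with the probe used alone, among them Cmtm2a (0.81 on the log2 scale with its other probe, adjusted p 0.528), Pcdh12 (-0.67, adjusted p 0.456), Cd247, Aif1, Nr1d1, Trib3, Btg2 and Klf15.

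Of the 24 glucocorticoid receptor targets 15 rose in KO muscle and none fell (16 and 0 adjusted over the list alone), including Mt1 (7.71-fold), Fkbp5 (6.68-fold) and Pdk4 (3.13-fold). Per1 (-0.08, SE 0.14, adjusted p 0.83) and Tsc22d3 (0.12, SE 0.13, adjusted p 0.71) did not pass. The median was 1.22 (camera adjusted p 6.2e-14; adjusted p = 0.096 with an estimated correlation), 1.17 with slide as a block, and 0.86, 1.14 and 1.44 within slides 4, 6 and 7. Of 23 atrophy genes 8 rose (12 adjusted over the list alone), with Foxo1 5.13-fold, Trim63 3.14-fold, Mstn 2.61-fold and Foxo3 1.93-fold higher, the last well above background on 1 of 4 vehicle arrays. Fbxo32 gave 1.07 (SE 0.36, adjusted p 0.082). The median was 0.31 (camera adjusted p 4.2e-05; adjusted p = 0.42 with an estimated correlation), 0.32 with the block, and 0.17, 0.32 and 0.47 within the slides. Of 29 amino acid catabolism genes 1 rose, Aldh6a1 (1.29-fold), and the list was not called (median 0.09, camera adjusted p 0.50); Bcat2 gave -0.24 (SE 0.19, adjusted p 0.59) and Prodh 0.32 (SE 0.11, adjusted p 0.096). Of 34 fatty acid genes 4 rose, Plin5 (3.58-fold), Ppara (2.69-fold), Ucp3 (2.23-fold) and Cd36 (1.70-fold), and 1 fell, with no call (camera adjusted p 0.19); Slc25a20 gave 0.04 (SE 0.15, adjusted p 0.94). Among glucose and glycogen genes Ppp1r3c rose 7.28-fold and Pfkfb1 1.77-fold, and Pdk2 and Gys1 fell 1.45-fold and 1.33-fold, with no call (camera adjusted p 0.89).

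Of 22 interferon-response genes 19 fell in KO muscle and none rose (20 and 1 adjusted over the list alone), with Ifi44 5.65-fold (2 of 4 dexamethasone arrays well above background), Iigp1 4.87-fold and Psmb9 4.15-fold lower. The median was -1.19 (camera adjusted p 1.3e-21; adjusted p = 0.037 with an estimated correlation), -1.05 with slide as a block, and -1.17, -1.29 and -1.18 within slides 4, 6 and 7. Of 19 inflammatory genes 3 fell, Ccl2 (3.92-fold), Cxcl9 (3.35-fold) and Tnfaip3 (1.42-fold), and the receptor gene Il1r1 rose 1.87-fold (7 and 2 adjusted over the list alone). The median was -0.51 (camera adjusted p 0.0013; adjusted p = 0.15 with an estimated correlation), -0.45 with the block, and -0.27, -0.57 and -0.41 within the slides. Of 16 clock genes 6 fell and none rose (7 and 1 adjusted over the list alone), among them Nr1d1 (2.93-fold), Bhlhe41 (2.86-fold) and Dbp (2.15-fold). The median was -0.25 (camera adjusted p 0.0012; adjusted p = 0.15 with an estimated correlation), -0.26 with the block, and -0.13, -0.37 and -0.35 within the slides. Of 15 immediate-early genes 3 rose, Maff (4.58-fold), Jun (1.68-fold) and Btg2 (1.65-fold). The median was 0.32 (camera adjusted p 0.010; adjusted p = 0.48 with an estimated correlation), 0.37 with the block, and 0.51, 0.19 and 0.41 within the slides.

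Of 13 endothelial markers 5 fell in KO muscle and none rose (5 and 1 adjusted over the list alone), including the angiopoietin receptor Tek (1.93-fold), Tie1 (1.71-fold), the VEGF receptor Kdr (1.67-fold) and Eng (1.55-fold). The median was -0.29 (camera adjusted p 0.014; adjusted p = 0.51 with an estimated correlation), -0.34 with the block, and -0.33, -0.32 and -0.18 within slides 4, 6 and 7. Of 10 smooth muscle and pericyte markers 4 fell (4 adjusted over the list alone), Notch3 (2.13-fold), Lmod1 (1.61-fold), Kcnj8 (1.37-fold) and Pdgfrb (1.29-fold), with a median of -0.14 (camera adjusted p 0.042; adjusted p = 0.52 with an estimated correlation), -0.14 with the block, which ended the call, and -0.21, -0.11 and -0.14 within the slides. Of 9 neutrophil markers only Il1r2 rose (3.64-fold); the list was not called (camera adjusted p 0.41), and its within-slide medians were 7.02, 0.06 and -1.41, the first from the slide with KO dexamethasone replicate 1. Leptin (Lep) was the only 1 of 11 adipocyte markers to rise (3.53-fold), and of 15 macrophage markers 1, Aif1, fell. The remaining lists were not called. Examples past the threshold in them were Mthfd2 (2.08-fold higher) and Trib3 (1.81-fold higher) of the amino acid stress genes, Col6a1 (1.66-fold lower) and Lum (1.73-fold lower) of the matrix genes, and Itga7 (1.49-fold lower) of the dystrophin-associated genes.

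In KO muscle 2528 features passed, 1338 higher and 1190 lower. With slide as a block 2586 passed, 1930 of them among the 2528, and all 80 named results kept their sign, 65 past the threshold. Since these results were chosen for passing on the same arrays, the kept signs are partly built in. Leaving out a single array ended the call of 24 of the 80 for at least 1 array. Of the 1653, 1274 and 1400 features called without slide 4, 6 or 7, 96.3%, 99.1% and 99.2% of the higher and 96.2%, 99.0% and 98.9% of the lower had the same sign on the slide left out. The count was 1418 with arrays scaled to their median.

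The responses of the 2 genotypes were set side by side across features, which are not independent replicates. The log2 changes had a Pearson correlation of 0.347 and a Spearman correlation of 0.273. Of the 1283 features higher in WT, 95.2% had the same sign in KO, where their median change was 0.53, and 749 passed there too. Of the 1426 lower in WT, 83.9% had the same sign in KO, with a median of -0.47, and 595 passed. Independent lists of these sizes would share 68.1 and 67.4. In all, 4 features passed in opposite directions. The correlation was 0.182 without KO vehicle replicate 3, 0.200 without KO vehicle replicate 4, 0.229 without KO dexamethasone replicate 3, 0.523 without KO vehicle replicate 2 and 0.554 with slide as a block. In the block fit KO dexamethasone arrays enter both responses through shared slides, which by itself can raise the correlation. The value of 0.554 is therefore not comparable with 0.347, where the 2 responses share no arrays.

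**Figure D3:**
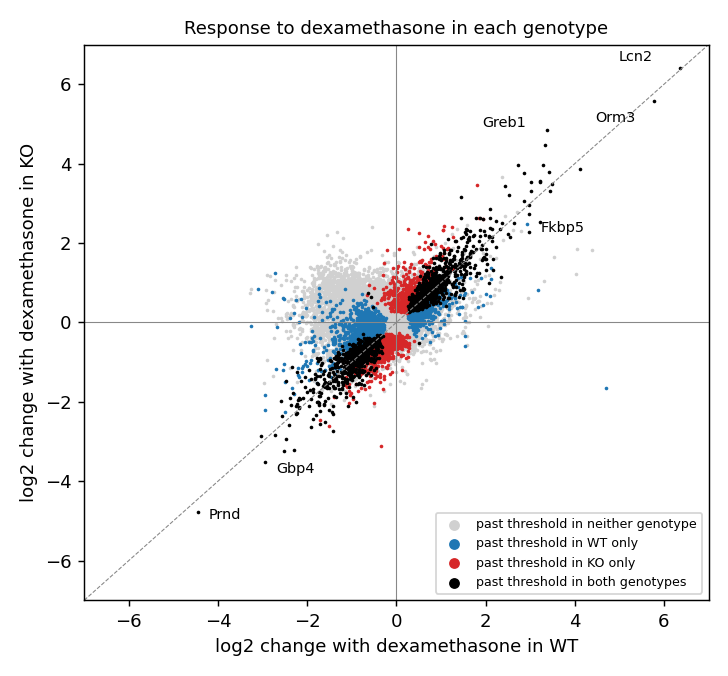
Log2 change with dexamethasone in WT (horizontal axis) and KO muscle (vertical axis), 1 point per feature, coloured by whether it passed the threshold in each genotype; the dashed line marks equal change. The Pearson correlation was 0.347, and Lcn2 rose 81.9-fold in WT and 84.6-fold in KO.

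No feature passed the test of a difference in response between genotypes (limma, genotype by treatment interaction), with 2868 features at an unadjusted p under 0.05. The smallest adjusted p was 0.0973, shared by 6 features, 2 of them without a gene symbol. Cth, cystathionine gamma-lyase, changed by 1.53 in WT and -0.35 in KO (log2; difference -1.89, SE 0.30). The ubiquitin ligase adaptor Spop changed by -0.82 and 0.05 (difference 0.88, SE 0.13), Slx4ip by -0.63 and 0.75 (1.39, SE 0.21; 0.45 with its other probe, adjusted p 0.575) and Itih5 by -0.75 and 0.08 (0.83, SE 0.13). Bcat2 had a difference of -1.04 (SE 0.28, adjusted p 0.21), Slc25a20 of -0.58 (SE 0.22, adjusted p 0.36), Prodh of -0.36 (SE 0.16, adjusted p 0.41) and Klf15 itself of 0.17 (SE 0.37, adjusted p 0.92). Fkbp5 (-0.24, SE 0.23), Pdk4 (0.03, SE 0.31), Fbxo32 (-0.02, SE 0.51), Trim63 (0.04, SE 0.25), Per1 (-0.37, SE 0.19) and Tsc22d3 (-0.17, SE 0.18) had adjusted p from 0.49 to 0.99. The count was 321 (185 higher, 136 lower) when slide was a random block, 0 with slide as a fixed block, 6 over probes well above background on all arrays, 2 with array weights, 1 with the deposited log2 values, 3 without KO vehicle replicate 4 and 1 without WT dexamethasone replicate 4. In simulated data 35.8% of features with an interaction of 1 log2 unit and 66.7% of those with 2 were recovered. For an interaction of 1 log2 unit slide as a fixed block recovered 0% with independent arrays and 10.4% with arrays correlated within slides, and slide as a random block 35.8% and 53.7%.

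As a group, the amino acid catabolism genes had lower responses in KO than in WT: the interaction was negative for 26 of 29 genes, with a median of -0.28 (camera adjusted p 7.9e-09; adjusted p = 0.058 with an estimated correlation) and -0.21 with slide as a block, and 3, all lower, passed adjusted over the list alone. Negative interaction medians were also called for fatty acid genes (-0.085, camera adjusted p 0.00099), interferon-response genes (-0.17, 0.012), clock genes (-0.15, 0.012), slow-fibre genes (-0.89, 0.042) and endothelial markers (-0.30, 0.0028), and a positive median for macrophage markers (0.46, 0.027). With an estimated correlation these 6 had adjusted p = 0.75, 0.69, 0.32, 0.82, 0.40 and 0.80. With the block their medians were -0.08, -0.14, -0.13, -1.46, -0.33 and 0.55, and the interferon-response call was lost. No slide held all 4 groups. Median, mean and camera's direction differed in sign for 35 of the 168 list tests, none of them called. The median interaction of all features was 0.11, and -0.18 when arrays were scaled to their median.

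Under vehicle, Adhfe1, a mitochondrial alcohol dehydrogenase family gene, was 45.5-fold lower in KO than in WT muscle (log2 change -5.51, SE 0.36) and well above background on 2 of the 4 KO arrays. Its other probe gave -2.06 (adjusted p 0.467). Cth was 12.9-fold lower (-3.69, SE 0.21), Prodh 8.28-fold (-3.05, SE 0.11) and Aldh6a1, methylmalonate semialdehyde dehydrogenase of valine breakdown, 4.08-fold (-2.03, SE 0.09). The FGF carrier Fgfbp1 (7.65-fold), Epop (5.50-fold), the neurotrophin Bdnf (4.27-fold), Epb41l5 (3.92-fold) and the glutathione transferase Gstm2 (3.82-fold, uncertain because of similar copies) were also lower. Only 4 genes met the naming rule as higher: Esr2 (at least 3.02-fold, not well above background in WT), the matrix gene Fbln2 (2.04-fold), which lies near Klf15 on the same chromosome, Plcg1 (1.52-fold) and Pdcd6ip (log2 change 0.58). Of these, Esr2 and Plcg1 changed direction with normexp. Of 8 named genes with other probes, 5 passed with the probe used alone: Adhfe1, Bdnf (-1.01 with its other probe, adjusted p 0.908), Epb41l5 (-0.15, adjusted p 0.958), Bcat2 (-0.58 and -1.13, adjusted p 0.724 and 0.056) and Pdcd6ip (0.17, adjusted p 0.842).

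Of 29 amino acid catabolism genes 8 were lower in vehicle-treated KO muscle and none higher (14 and 0 adjusted over the list alone). Besides Prodh and Aldh6a1 these included isovaleryl-CoA dehydrogenase Ivd (2.56-fold), Bckdhb, a subunit of the branched-chain keto acid dehydrogenase (2.54-fold), and Bcat2 (2.24-fold). The median was -0.42 (camera adjusted p 3.5e-20; adjusted p = 0.0034 with an estimated correlation), -0.29 with slide as a block, and -0.28, -0.46 and -0.34 within slides 4, 6 and 7. No member of another list passed; adjusted over the list alone, 4 glucose and glycogen genes and 1 glucocorticoid receptor target were lower, and 1 respiratory chain gene, 1 endothelial marker and 2 smooth muscle and pericyte markers higher. Shifts were called for endothelial markers (median 0.23, camera adjusted p 8.2e-06; adjusted p = 0.14 with an estimated correlation), smooth muscle and pericyte markers (0.19, 1.8e-05; adjusted p = 0.096 with an estimated correlation), interferon-response genes (0.16, 3.9e-05; adjusted p = 0.43 with an estimated correlation), slow-fibre genes (0.73, 0.0023; adjusted p = 0.66 with an estimated correlation) and nerve and Schwann cell markers (0.16, 0.016; adjusted p = 0.69 with an estimated correlation). With the block these medians were 0.24, 0.21, 0.18, 0.62 and 0.35. Within slides 4, 6 and 7 they were 0.38, 0.06 and 0.35 for endothelial, 0.36, 0.04 and 0.34 for smooth muscle, 0.27, 0.61 and -0.13 for interferon-response, 1.53, -0.64 and 1.10 for slow-fibre, and 0.31, 0.35 and 0.38 for nerve genes, so that the interferon and slow-fibre shifts changed sign on 1 slide each. Fkbp5 (0.11, SE 0.16), Per1 (0.22, SE 0.14), Tsc22d3 (0.12, SE 0.13), Pdk4 (-0.40, SE 0.22), Fbxo32 (-0.53, SE 0.36), Trim63 (-0.20, SE 0.18) and Slc25a20 (-0.24, SE 0.15) did not pass. In all, 65 features passed, 6 higher and 59 lower, and 21 with slide as a block, of which 19 were among the 65. Simulated changes of 1 log2 unit were recovered at 11.9% to 47.8% by the block fit. Of 17 named results, Bdnf, Bcat2, Plcg1 and Pdcd6ip lost their call without at least 1 of the arrays. Of the 37, 27 and 39 features called lower without slide 4, 6 or 7, 94.6%, 100% and 100% were lower on the slide left out.

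Under dexamethasone, Adhfe1 was 87.9-fold lower in KO muscle (log2 change -6.46, SE 0.36), with 1 of 4 KO arrays well above background, and Cth was 47.9-fold lower (-5.58, SE 0.21). The acyl-CoA thioesterase Acot1 was 17.7-fold lower, Fgfbp1 14.2-fold, Bdnf 9.95-fold (3 of 4 KO arrays well above background), the transcription factor Klf10 9.31-fold, Epop 8.80-fold and Gstm7 6.76-fold (1 of 4 KO arrays). Prodh changed by -3.41 (SE 0.11). Acot1 and Gstm7 have closely similar copies and are uncertain. The other probes of Adhfe1 (-2.04, adjusted p 0.203), Bdnf (-0.70, adjusted p 0.882) and Cpt1a (-0.47, adjusted p 0.371) did not pass, 3 of 5 named genes with other probes. Rises were smaller: Ica1l (2.39-fold), the growth factor Fgf10 (2.23-fold), Fbln2 (2.21-fold), Sncg (2.15-fold), Lao1 (2.15-fold), Traf3ip1 (2.10-fold), Megf9 (2.09-fold), the collagen crosslinking enzyme gene Loxl2 (2.02-fold) and Ddx23 (2.00-fold) were higher, as was Fsip1, well above background on 2 of 4 KO arrays and no WT array, with no fold given. Leaving out any 1 of 12 arrays ended the call of Traf3ip1, any 1 of 9 that of Fsip1 and any 1 of 7 that of Ica1l and Fgf10. It took any 1 of 6 for Megf9 and Sncg and of 2 for Loxl2, while Fbln2, Lao1 and Ddx23 kept their call. Fgf10, Traf3ip1, Megf9, Ddx23 and Fsip1 changed direction with normexp.

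Of the 29 amino acid catabolism genes 17 were lower in KO muscle under dexamethasone and none higher (20 and 0 adjusted over the list alone). Aldh6a1 was 4.73-fold lower (-2.24, SE 0.09), Bcat2 4.61-fold (-2.20, SE 0.19) and Dbt, another subunit of the keto acid dehydrogenase, 3.48-fold. The median was -0.59 (camera adjusted p 2.6e-34; adjusted p = 0.00037 with an estimated correlation), -0.53 with slide as a block and -0.42 within slide 8, the only slide with both groups. Of 34 fatty acid genes 3 were lower, Ucp3 (1.99-fold), Cpt1a (1.81-fold) and Slc25a20 (1.77-fold), and the coactivator gene Ppargc1a was 1.45-fold higher (11 and 1 adjusted over the list alone). The median was -0.22 (camera adjusted p 7.4e-08; adjusted p = 0.51 with an estimated correlation), -0.18 with the block and -0.17 within the slide. Of 23 glucose and glycogen genes 1, the fructose bisphosphatase Fbp2, was lower (2.88-fold; 2 adjusted over the list alone), and of 16 clock genes 1, Arntl (2.15-fold; 4 adjusted over the list alone). The medians of these lists were -0.10 and -0.01 (camera adjusted p 0.0012 and 0.025; adjusted p = 0.56 and 0.40 with an estimated correlation), -0.05 and -0.09 with the block, which ended the call of the glucose and glycogen genes, and 0.04 and -0.01 within the slide. No atrophy gene of 23 passed, with a median of -0.16 (camera adjusted p 0.014; adjusted p = 0.69 with an estimated correlation), -0.09 with the block and -0.03 within the slide. The endothelial phosphatase gene Ptprb was 1.78-fold higher. Fkbp5 (-0.13, SE 0.16), Per1 (-0.15, SE 0.14), Tsc22d3 (-0.05, SE 0.13), Pdk4 (-0.37, SE 0.22), Fbxo32 (-0.55, SE 0.36) and Trim63 (-0.17, SE 0.18) did not pass.

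**Figure D4:**
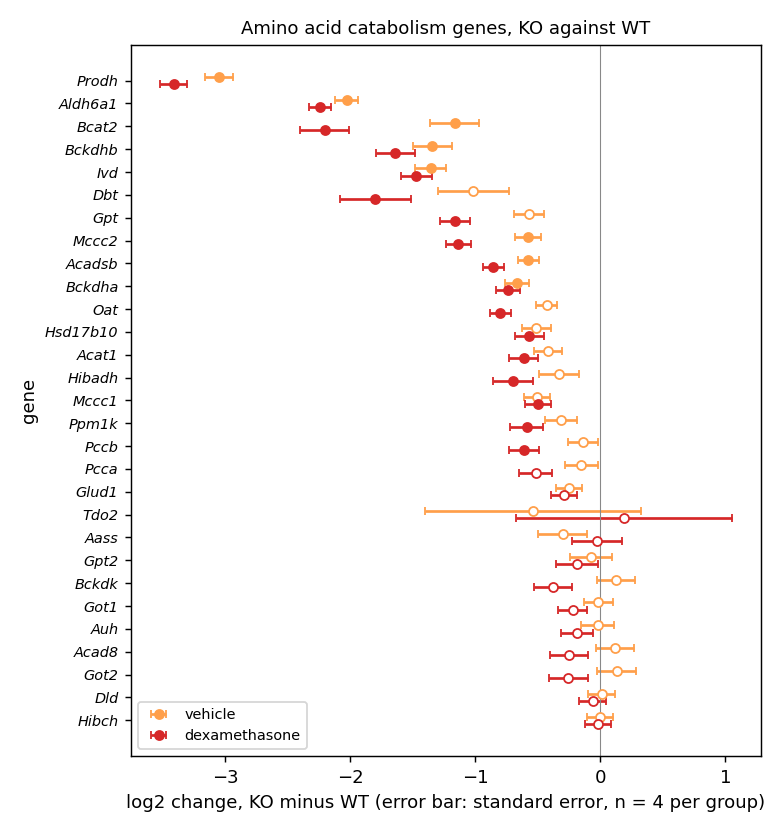
Log2 difference between KO and WT muscle (horizontal axis) for the 29 measured amino acid catabolism genes (vertical axis) under vehicle and dexamethasone, with the standard error (n = 4 per group). Filled points passed the threshold: 8 genes under vehicle and 17 under dexamethasone, all lower in KO.

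In all, 460 features passed under dexamethasone, 240 higher and 220 lower. Of 207 features called without the arrays of slide 8, 97.3% of the higher and 100% of the lower had the same sign on that slide. With slide as a block, a fit that recovered 0% to 32.8% of simulated changes of 1 log2 unit, 45 passed, 37 of them among the 460. Of 30 named results 10 lost their call without at least 1 of the arrays. The count was 285 without KO dexamethasone replicate 3, 295 without KO dexamethasone replicate 2 and 232 without the 2 arrays with raised neutrophil markers. The share of higher features, 52.2%, was 10.2% when arrays were scaled to their median, under which the median of all features was -0.14, and 39.4% with quantile normalization.

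Averaged over both treatments (n = 8 arrays per genotype), Adhfe1, well above background on 3 of 8 KO arrays, was 63.3-fold lower in KO muscle (log2 change -5.98, SE 0.26), Cth 24.9-fold, Klf15 14.8-fold, Fgfbp1 10.4-fold, Prodh 9.39-fold, Acot1 7.76-fold, Epop 6.96-fold, Bdnf 6.52-fold, Epb41l5 4.88-fold and Gstm2 4.58-fold. Fbln2 (2.12-fold), Lpgat1 (1.51-fold) and Mblac1 (1.23-fold) were the genes named as higher. Of 7 named genes with other probes 4 passed with the probe used alone: Adhfe1 (-2.05 with its other probe, adjusted p 0.082), Bdnf (-0.85, adjusted p 0.906), Epb41l5 (-0.06, adjusted p 0.997) and Cpt1a (-0.23, adjusted p 0.744). Of the 29 amino acid catabolism genes 16 were lower and none higher (19 and 0 adjusted over the list alone), with Aldh6a1 4.40-fold, Bcat2 3.21-fold and Bckdhb 2.81-fold lower. The median was -0.50 (camera adjusted p 2.8e-39; adjusted p = 0.00035 with an estimated correlation) and -0.40 with slide as a block. Of 34 fatty acid genes Ucp3 (1.60-fold), Cpt1a (log2 change -0.58) and Slc25a20 (1.44-fold) were lower and Ppargc1a (1.31-fold) higher, with a median of -0.20 (camera adjusted p 2.9e-07; adjusted p = 0.54 with an estimated correlation) and -0.11 with the block. Of 23 glucose and glycogen genes 3 were lower, Fbp2 (2.20-fold), Pfkfb1 (1.40-fold) and the glucose transporter Slc2a4 (1.24-fold), with a median of -0.08 (camera adjusted p 0.0058; adjusted p = 0.66 with an estimated correlation) and -0.06 with the block. Arntl was 1.76-fold lower.

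Other called shifts in the averaged comparison had no member past the threshold. They were atrophy genes (median -0.13, camera adjusted p 0.0064), interferon-response genes (0.10, 0.037), endothelial markers (0.10, 0.042), smooth muscle and pericyte markers (0.15, 0.0031), adipocyte markers (0.34, 0.033) and nerve and Schwann cell markers (0.25, 0.014). With an estimated correlation these had adjusted p = 0.65, 0.80, 0.58, 0.28, 0.80 and 0.69, and with slide as a block their medians were -0.09, 0.17, 0.22, 0.15, 0.60 and 0.40, the block ending the call of the smooth muscle and pericyte markers; slide as a random block ended that of the atrophy genes. Among lists not called here, the medians here were 0.08 for extracellular matrix, -0.07 for fast-fibre, 0.02 for amino acid stress, -0.04 for lymphocyte, -0.45 for neutrophil, -0.42 for erythroid, 0.12 for tendon and -0.12 for sex-linked genes, with camera adjusted p from 0.11 to 0.89. Altogether 337 features passed, 93 higher and 244 lower, and 71 with slide as a block (31.3% to 55.2% recovery of simulated changes of 1 log2 unit), 63 of them among the 337. Of 24 named results, Slc2a4, Ppargc1a, Slc25a20 and Cpt1a lost their call without at least 1 of the arrays. The count was 210 without the 2 arrays with raised neutrophil markers. The share of higher features was 27.6%, and 12.6% when arrays were scaled to their median.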

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

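Of the tests in this part, the amino acid genes' tests with slide as a block and with quantile normalization, and the splits at an unadjusted p, were chosen after the result was seen. In each group of 4 arrays, the gap between the farthest array and its nearest neighbour was set against the group's whole range, and a ratio above Dixon's critical value for 4 values marked the array as standing apart. Chance flags about 1 in 20 groups: 38 of 600 groups tested stood apart, against 30 by chance. Each ratio is given with the array it belongs to. They fell on all 8 slides, with 2 to 7 on each.

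Klf15 signal of probe A_52_P64383 was lowest on KO dexamethasone replicate 2 (0.26 against a median of 0.64 on the other 3 arrays, ratio 0.850), where Fbln2 was also lowest (0.941). On KO dexamethasone replicate 4, Ccl2 (0.930), Ccl7 (0.862) and Greb1 (0.855) were highest and Maff (0.901) was lowest. Fam167a was highest on KO dexamethasone replicate 1 (0.957). On KO vehicle replicate 4, Acot1 (0.832), Aldh1l1 (0.883) and Ivd (0.945) were highest and Folr2 (0.837) was lowest. On KO vehicle replicate 2, Lin52 (0.854), Ppargc1a (0.852) and Ppp1r3c (0.852) were highest and Prss42 (0.915) was lowest.

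In WT muscle after dexamethasone, replicate 1 was highest for Ica1l (0.909) and Il1r1 (0.885) and lowest for Ddx23 (0.844), Pdk4 (0.851) and Slx4ip (0.847). Replicate 2 was highest for Cd36 (0.877) and Fam83d (0.831) and lowest for Fgfbp1 (0.875) and Irs1 (0.954). Replicate 3 was highest for Plcg1 (0.911) and lowest for Tsc22d3 (0.911), and replicate 4 was highest for Cxcl10 (0.917) and lowest for Ndufa9 (0.891). Under vehicle, WT replicate 1 was highest for Camkv (0.846) and Kcnj8 (0.857) and lowest for Mblac1 (0.919). Replicate 2 was lowest for Greb1 (0.887) and Ica1l (0.8294). Replicate 3 was highest for Slc2a4 (0.888) and lowest for Btg2 (0.889), Sncg (0.833) and Traf3ip1 (0.922), and replicate 4 was highest for Slc25a29 (0.889).

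The response of 7 gene lists to dexamethasone differed between genotypes by camera's test of the interaction. The median interaction was -0.28 for amino acid catabolism, -0.085 for fatty acid, -0.17 for interferon-response, -0.15 for clock, -0.89 for slow-fibre and -0.30 for endothelial genes, and 0.46 for macrophage markers. None had an adjusted p under 0.05 with an estimated correlation, where they ranged from 0.058 for amino acid catabolism to 0.82 for slow-fibre genes.

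The amino acid catabolism genes were also lower in KO muscle averaged over treatments, with a list median of -0.50. A difference between slides as the whole cause was argued against, since with slide as a fixed block the median was -0.40 (camera p 4.5e-21 with the preset correlation). Scaling as the whole cause was argued against by quantile normalization, which does not shift all features of an array alike: relative to all features the list lay at -0.45, against -0.49. A lower share of muscle fibres as the whole cause would lower other fibre genes alike, but 42 fast-fibre and respiratory chain genes had a median of -0.040. The SE of their mean, taken over genes, was 0.016 and does not measure the spread between animals. A small loss stays open, since the fast-fibre genes alone had a median of -0.07. Markers of adipocytes (0.34), nerve (0.25), smooth muscle (0.15) and endothelium (0.10) had positive medians. All of these lists were called by camera with the preset correlation. With an estimated correlation their camera adjusted p = 0.80, 0.69, 0.28 and 0.58. A dependence of these genes on Klf15 in muscle remains a hypothesis consistent with these tests, and other differences between WT and KO animals were not tested.

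Each count of genes was set against other splits of the same arrays, over 25115 features without missing values. The splits exchanged arrays between slides, although arrays of different groups on 1 slide deviated together, so they test chance without regard to slide. In that sense chance was argued against for dexamethasone in WT (2700 features, at most 0 in the other splits), dexamethasone in KO (2522, at most 318), KO against WT under vehicle (65, at most 0) and under dexamethasone (461, at most 55). The real split was the 1 of 35 with the largest count each time, the smallest share that 35 splits can give. For dexamethasone in WT it also parted slides, since replicates 1, 3 and 4 lay on slides without a WT vehicle array. For KO against WT under dexamethasone it parted slides too. There WT replicates 1, 2 and 3 and KO replicates 1, 2 and 4 lay on slides without a dexamethasone array of the other genotype. With slide as a fixed block the counts for the 4 comparisons were 766, 2586, 21 and 45, in the order given above. For the average over treatments the real split was the 1 of 100 with the largest count (338, at most 265 in another). The split with 265 put the 3 arrays of slide 7 and WT dexamethasone replicate 1 on the same side, as the first principal component did. With slide as a block the real count was 71. For the interaction the real count was 0, which all 100 of 100 splits must reach, so that count says nothing about chance. At an unadjusted p under 0.05 the real split gave 2856 features, and 12 of 100 splits, the real one included, gave as many (at most 5110), so chance could not be excluded. A single other split called 663 features past the threshold, which points to a structure of the samples other than the groups. It set the 4 vehicle arrays highest on the second principal component (36.9 to 53.3, the others at most 34.6) and the 4 dexamethasone arrays lowest on it (-76.3 to -30.5, the others at least -14.0) against the rest. That component, 22.6% of the variance, followed the slides. Arrays of slides 1, 2, 3 and 8 lay from -106 to -30.5 on it, and all others from -14.0 to 55.3. WT dexamethasone replicates 1, 3 and 4 and no WT vehicle array lay on those slides, so the component overlaps with dexamethasone in WT. Of the KO arrays only dexamethasone replicate 3 and vehicle replicate 2 lay there. The component thus also overlaps with KO against WT under dexamethasone and with the interaction. Why these slides differ was not tested. With slide as a random block the interaction gave 301 features and at most 14 in another split (1 of 100). The splits exchange arrays between slides, while that model takes arrays of a slide as correlated, so they cannot exclude chance in it. Slide as a fixed block gave 0 and recovered 0% to 10.4% of simulated interactions of 1 log2 unit, against 35.8% to 53.7% for the random block.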

How the results depend on the processing

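Settings chosen after the data were seen were leaving out the 3 arrays marked for evaluation, slide 7 or the 2 arrays with raised neutrophil markers, and the median signal with local background subtracted or uncorrected. Klf15 was lower in KO under each setting run. Of the 9 main results (6 counts of features, the Klf15 level, the correlation between responses and the number of lists called), each one recomputed stayed within its bounds with quantile normalization, no filter on dim probes, the mean of all probes, eBayes with trend and subtracted local background. The same held with scan date as a block. That block only removes WT dexamethasone replicate 3, the sole array of its date, so it does not test an effect of the date. Of 283 named gene results, 257 kept their side of the threshold with quantile normalization, 230 with scaling to the median, 252 with the deposited log2 values, 176 with slide as a fixed block and 129 with normexp. Of those counted, the ones past the threshold also kept their direction. For results past it in neither fit, direction was not compared. The number of lists called can hide lost calls. Of the 46 called list tests, 34 kept their call and direction with quantile normalization, 45 with scaling to the median and 38 with the deposited log2 values. With slide as a fixed block 39 did, and with normexp 33. Where a probe was below background on all arrays of a group a fold is only a bound. Of the 283 results, 254 had a probe well above background on all arrays, and 246 of these kept their side of the threshold there. Signal over background thus limits the genes lowest in KO, such as Adhfe1, and the interaction of dim genes.

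Counts are given against 2709 features for dexamethasone in WT, 2528 in KO, 65 for KO against WT under vehicle, 460 under dexamethasone, 337 averaged and 0 for the interaction. Unless stated, the cause was not tested. Scaling to the median gave 1418 in KO, 38 under vehicle, 216 under dexamethasone and 167 averaged. Normexp gave 183, 404, 17, 49 and 61 in the same order, and 79 lists in place of 46. Array weights gave 4884 in WT, 161 under vehicle, 531 averaged and 2 for the interaction. Slide as a random block gave 5027 in KO, 433 under vehicle, 957 under dexamethasone, 983 averaged and 321 for the interaction. Slide as a fixed block, which recovered fewer simulated changes than the other fits, gave 766 in WT, 21 under vehicle, 45 under dexamethasone and 71 averaged. Fits of only the groups compared, which rest on fewer arrays, gave 1435 in WT, 30 under vehicle and 111 under dexamethasone. A threshold of 0.10, looser by construction, gave 818 under dexamethasone, 539 averaged and 6 for the interaction. The interaction count was also 6 over probes well above background on all arrays, and 1 each with the deposited log2 values and the uncorrected median signal. Without the 3 marked arrays the counts were 1261 in KO, 111 under dexamethasone and 155 averaged. Without slide 7 they were 1400 in KO, 40 under vehicle and 165 averaged, and without the 2 arrays with raised neutrophil markers 232 under dexamethasone and 210 averaged, all with fewer arrays. The correlation between responses, 0.347, was 0.518 over probes well above background on all arrays. It was 0.554 with slide as a fixed block, where both responses draw on KO dexamethasone arrays, so that value is not comparable. Lists called fell to 4 with an estimated correlation and 21 with fry.

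Among named results and lists past the threshold in the main fit, directions were reversed with normexp only. The log2 changes became 0.090 for Fam167a and 0.019 for Ugt2a1 with dexamethasone in WT, and 0.17 for Dhrs2 in KO. For KO against WT they became -0.30 for Esr2 and -0.22 for Plcg1 under vehicle, and -0.58 for Fsip1, -0.32 for Fgf10, -0.28 for Traf3ip1, -0.33 for Megf9 and -0.15 for Ddx23 under dexamethasone. Camera's direction turned for atrophy genes (median -0.026) and glucose genes (0.058) under dexamethasone, and for atrophy (0.0070), fatty acid (-0.036) and glucose genes (0.089) averaged. The fitted background mean ranged from -313 to 4.31 against median local backgrounds of 17 to 21.5, and the median SD within groups was 0.50 against 0.278, so a poor background fit is a candidate cause. Neither added background setting reversed a named result past the threshold or a called list.

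A single array left out ended the call of 31 of 84 named results for dexamethasone in WT, 24 of 80 in KO, 4 of 17 for KO against WT under vehicle, 10 of 30 under dexamethasone and 4 of 24 averaged. Leaving out each array in turn gave 1627 to 2664 features for dexamethasone in WT, 1809 to 2657 in KO, 44 to 70 for KO against WT under vehicle, 285 to 480 under dexamethasone, 234 to 345 averaged and 0 to 3 for the interaction. The Klf15 change ranged from -3.98 to -3.78, the correlation between responses from 0.182 to 0.523 and the lists called from 39 to 54.

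With the replicate number as a block, 290 features passed for KO against WT under dexamethasone and 200 averaged; the other counts stayed within 1.5 times. The numbers did not pair the arrays: same-numbered arrays of different groups had a median correlation of -0.04 in their deviations from group means, 5 of 24 pairs were over 0.1, and 1 of 16 arrays was closest to its own number. Arrays of different groups on 1 slide were over 0.1 in 11 of 11 pairs, with a median of 0.50.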

Other observations

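Of the tests in this part, those on pairs without members of 1 gene family and on erythroid markers were chosen after the result was seen. Several genes lower in KO muscle averaged over treatments lay next to another such gene, in the order of the measured genes. Adhfe1 (log2 change -5.98; -2.05 and not past the threshold with its other probe) lay next to Rrs1 (-1.21, SE 0.07), a ribosome biogenesis gene, and Aldh6a1 (-2.14) next to Lin52 (-1.48, SE 0.06), a subunit of the DREAM complex that represses cell cycle genes. Pole (-1.78), the catalytic subunit of DNA polymerase epsilon, lay next to Pxmp2 (-1.25), a peroxisomal membrane protein gene, and Sfxn2 (-1.75), a mitochondrial carrier gene, next to Arl3 (-0.37). The mitochondrial carrier genes Slc25a29 (-1.28) and Slc25a47 (-1.22) were neighbours, as were the glutathione transferase genes Gstm3 (-0.83), Gstm2 (-2.19) and Gstm1 (-0.81), which are uncertain because of their similar copies. Smaller changes were seen for Ddt (-0.96) and Gstt3 (-0.29), Rpa1 (-0.35) and Smyd4 (-0.43), and Pcsk4 (-0.60), Reep6 (-0.64) and Plk5 (-0.52). These genes were chosen for their position after their values were seen, and each passed the threshold (limma, adjusted p from 3.3e-10 to 0.044, n = 8 arrays per genotype).

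Placement of the 182 lower genes by chance was argued against: they formed 12 neighbouring pairs, and 10000 random sets of measured genes had a median of 2 and at most 10 (permutation p = 0.0001, the smallest they can give). Cross-hybridisation within gene families was argued against as the whole cause, since 9 pairs were left without pairs of 1 family, against at most 8 in random sets (permutation p = 0.0001, again the smallest). Near Klf15, whose own neighbour Aldh1l1 (-1.03) made 1 of the pairs, 4 of 100 genes passed (Aldh1l1, Fbln2 at 1.08, Suclg2 at -0.41 and Crbn at -0.30) against 235 of 15076 elsewhere. With a Fisher exact p of 0.0732 and 1 pair there, an effect of the region carried along with the targeted allele on these 4 genes cannot be told apart from an effect of Klf15. Control elements shared by neighbouring genes may account for the other pairs, a hypothesis that was not tested.

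Neutrophil markers were raised on WT dexamethasone replicate 3 and KO dexamethasone replicate 1, with S100a9 at 7.41 and 6.15 and Mpo, an early granule gene, at 3.43 and 2.44 (log2, relative to the 75th percentile). A list of bone marrow precursor genes, 10 of them measured, 9 well above background on at least 1 of the other 14 arrays and 0 in another list, had a median 2.83 higher on the lower of these arrays than on any other array (2.94 against 0.109), and Dntt alone of them was not higher there (-0.31). Neutrophils without other blood cells were argued against, since the erythroid median of the lower array lay 0.99 above the highest other array (1.43 against 0.443). Bone marrow RNA in these 2 samples is a candidate source that the values fit; the labels name no sort that would remove it, and blood with immature cells was not tested. Il1r2 (-0.67) and Lcn2 (-0.24) were not higher on these arrays than on every other array, and the counts without both arrays were 232 features for KO against WT under dexamethasone and 210 averaged.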
